A study of Homo sapiens with 4 samples.

How the data were processed

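RNA was measured by sequencing in primary human cardiac fibroblasts (HCF), cells grown from heart tissue and bought as a commercial cryopreserved stock. The cells received a small interfering RNA (siRNA) against CDCP1 or a non-targeting control siRNA and were collected 48 h later. Each group had 2 libraries, 4 in all, made with the Illumina TruSeq RNA kit. The labels call the libraries of a group only replicate 1 and replicate 2. Whether they came from separate cultures, or from more than 1 donor, is not stated in the sources used here, so the spread between them may be technical. The p-values of single genes below measure a difference against that spread, pooled in large part over genes (39.39 prior degrees of freedom). No p-value below covers more variation between cultures or donors than these libraries hold. The siRNA sequences, and whether each was a single duplex or a pool, are not given in the sources used here either.

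Per the labels, the authors used FastQC, STAR, featureCounts and edgeR with the human genome build hg38; no versions or settings were stated, nor the annotation release. The deposited table holds expected counts, that is, read counts per Ensembl gene without normalization, in the layout of featureCounts. The counts include fractions, which arise where 1 read was shared between overlapping genes or between several alignments. Of the non-zero values, 58.05% to 59.07% per library were whole numbers. Counts were rounded to whole numbers for the tests, after which library totals decreased by 0.000811% or less. For genes whose exons overlap those of another gene, part of the signal may have been divided between both, and overlaps above 20% of exonic length are given beside the genes named. The table has 64561 genes, of which 58275 (90.26%) have an identifier in GENCODE 29, used here for symbols, biotypes and 3′ UTRs. These carried at least 99.992% of the counts in each library, and 98.73% of them had the same start and end in both sources. Intervals and standard errors of fold changes come from the spread between libraries, pooled in large part over genes. They cover neither the choice of siRNA nor the choice of donor.

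Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count of 10), libraries were scaled by the trimmed mean of M-values (TMM), and a two-group quasi-likelihood model was fitted. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Unless another tool is named, every adjusted p for a gene is from this edgeR quasi-likelihood test. Levels are TMM-normalised CPM, counts scaled to a common library size, given as the mean ± SD of 2 libraries. Fold changes are CDCP1 siRNA over control siRNA on the log2 scale with their SE.

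The text names CDCP1 and IL1RL1 whatever their result. It further names the 12 protein-coding genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups. In each gene list the rule takes up to 4 members with the smallest p. These rules take 139 genes, not all of which are named in the text. Further genes, 168 in total with these, were chosen after their values were seen and are marked so. In each gene named as having risen or fallen, both CDCP1 siRNA libraries lay on the same side of both control libraries.

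A total of 32 gene lists was fixed before the data were examined. They cover CDCP1 signalling partners, collagens and matrix proteins, collagen processing and crosslinking, contractile and myofibroblast genes, and matrix proteases and inhibitors. For signalling they cover TGF-beta, BMP and YAP/TAZ targets, growth factor receptors and ligands, immediate early genes with ERK feedback, and FOXO targets. For the cell cycle and inflammation they cover DNA replication, mitosis, p53 targets with cell cycle inhibitors, the interferon response, inflammatory cytokines with NF-kB targets, and the receptors and ligands of IL1 and IL33. Heart failure plasma markers and cardiac fibroblast identity make 1 list each. Others cover cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, the unfolded protein and integrated stress response, autophagy and lysosome, apoptosis regulators, adhesion and integrins, and the markers of endothelial cells, of pericytes and smooth muscle, of cardiomyocytes, of leukocytes, and of epicardium and mesothelium. The 30 lists with at least 5 tested members were tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, two-sided, adjusted over the lists. Camera with the correlation estimated from the data, which has few degrees of freedom with 4 libraries, and fry were run beside it. Fry asks whether the genes of a list move on balance one way, without comparing them with other genes.

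The alternatives were size factors as in DESeq2 (RLE), library totals alone, no filter on low counts, a filter at 1 CPM in 2 libraries, DESeq2 1.42.0, limma voom, robust estimation, the replicate number as a block, an adjusted p under 0.01, and each library left out in turn. Without 1 library, its group has a single one, which is assumed to vary like those of the other group.

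The seeds of siRNAs can repress unintended transcripts through matching sites in 3′ UTRs. All 7-base sites present in the longest annotated 3′ UTR of at least 100 of 12053 protein-coding genes were therefore related to the log2 fold changes, with UTR length, base composition and expression level regressed out. The statistic of each site, a difference between genes with and without it in units of its standard error, was set against the most extreme of all sites in 100 shuffles of the fold changes over genes. Sites were then added in turn until none passed the shuffles, which left 5 leading sites, 3 going with lower and 2 with higher values. Of the 3, ATCTATA and TCTATAA overlap in all but their end bases and may mark the same site. The statistic of TCTATAA went from −8.3 to −5.88 once the sites added before it were regressed out.

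The pipeline was tested on simulated data of the same size with 200 changed genes among 19298, and with the oxidative phosphorylation list raised besides. Calls among the members of that list were not counted as false. The test recovered 63.64% of genes changed 1.5-fold, 72.31% of those changed 2-fold and 93.94% of those changed 4-fold, and 7.216% of its 194 calls were false. A list made to rise ranked 1 among all lists with 0 others called. Genes were simulated independently of each other, so this did not test the preset correlation between genes. A planted 7-base site ranked 1 among all sites. Its planted effect of 0.3 log2 was larger than that of any leading site, of which ATCTATA had the largest adjusted difference, −0.206. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for the tables and sites. No value column of the deposited table was left out.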

Results

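The transcriptome of primary human cardiac fibroblasts was measured 48 h after transfection with an siRNA against CDCP1, which encodes the transmembrane glycoprotein CUB domain containing protein 1, or with a non-targeting siRNA. Each group had 2 libraries. Control replicates 1 and 2 held 38798777 and 34078629 counts over 27981 and 28043 genes with a count. CDCP1 siRNA replicates 1 and 2 held 42156048 and 40016304 over 26742 and 26847 genes. Mitochondrial genes took 3.20% and 2.97% of the counts in the control libraries and 3.42% and 3.65% in the CDCP1 siRNA libraries. The fibronectin gene FN1, chosen after its value was seen, alone took 6.76% and 6.32% in the controls and 4.59% and 5.13% after CDCP1 siRNA. Across genes within libraries, which are not independent replicates, log2 CPM correlated with Pearson's r of 0.991 between the control libraries, 0.988 between the CDCP1 siRNA libraries, and 0.965 to 0.968 between libraries of different groups.

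The single comparison asked how the transcriptome of cardiac fibroblasts changes when CDCP1 is knocked down. CDCP1 was 7.81-fold lower, and IL1RL1, the gene of the IL-33 receptor ST2, was 16.4-fold lower. Counts are per gene and do not separate the transcripts of a gene. Of the genes tested, 31 of 32 of mitosis, 24 of 30 of DNA replication and 24 of 32 of the interferon response fell, while 11 of 18 that modify and crosslink collagen and 17 of 25 of adhesion rose. Each of these 5 lists was called against all other genes, and each had an adjusted p = 0.441 with an estimated correlation.

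CDCP1 (ENSG00000163814) lies on chromosome 3 from 45082278 to 45146422 on the minus strand of hg38, and its annotated exons overlap no other gene. It had 7.76 ± 0.137 CPM in the control libraries and 0.990 ± 0.108 CPM in the CDCP1 siRNA libraries (SD, n = 2 each). The log2 fold change was −2.97 (SE 0.22, 95% interval −3.41 to −2.52), with an adjusted p of 8.88e-15 in the edgeR quasi-likelihood test. IL1RL1 (ENSG00000115602, chromosome 2 from 102311502 to 102352037, plus strand) had 257.1 ± 12.5 CPM in the controls and 15.6 ± 1.12 CPM after CDCP1 siRNA. Its log2 fold change was −4.04 (SE 0.10, adjusted p = 5.34e-30). Of its exonic length, 1.65% overlaps IL18R1, the neighbouring gene of an IL-18 receptor chain. The longest annotated 3′ UTR of IL1RL1 holds GAGAAAG, 1 of the 3 leading 7-base sites that went with lower values across all genes. That of CDCP1 holds none of the 5 leading sites. Which 3′ UTRs these cells use was not examined. An siRNA may target the CDCP1 transcript at any point. The whole CDCP1 transcript holds ATCTATA and TCTATAA, which overlap in sequence, 1 time each, and GAGAAAG 2 times. It holds the leading sites that went with higher values 0 times. Of 2936 transcripts of similar length, 24.93%, 28.95% and 60.59% hold ATCTATA, TCTATAA and GAGAAAG, and 26.19% and 35.73% hold AGCCTTA and CACATCA, the sites absent from it.

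**Figure D1:**
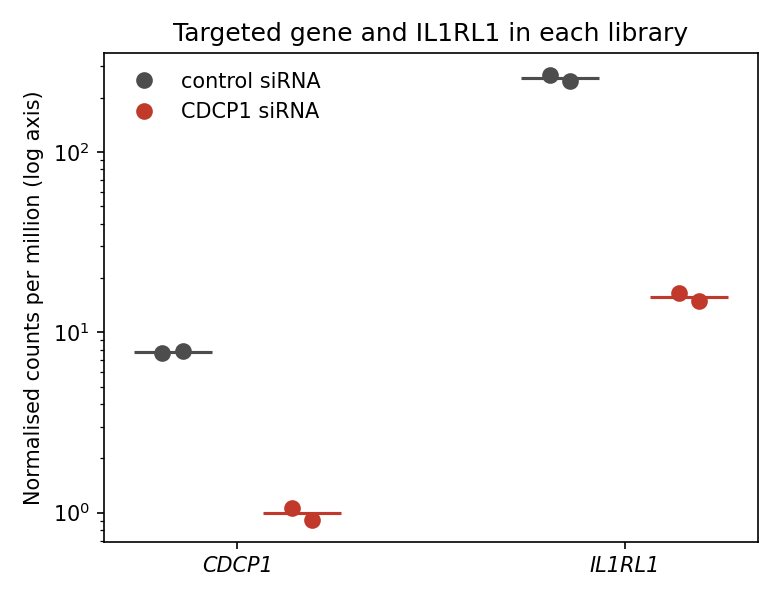
Normalised level in CPM (log axis) of CDCP1 and IL1RL1 in each library; points are libraries and lines are the means of 2 libraries per group. Both genes were lower in both CDCP1 siRNA libraries than in either control library.

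Of 19298 genes tested, 4084 were higher and 3756 were lower with CDCP1 siRNA, together 40.6% of the genes. Among protein-coding genes 3433 rose and 3162 fell of 13770 tested. At least 1 log2 unit of change was reached by 933 of the genes that rose and by 1152 of those that fell, and at least 2 units by 177 and 279. In 69.5% of the tested genes the libraries of the groups did not overlap, where chance gives 33.3%. The biological coefficient of variation was 0.0821.

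The 12 largest falls among genes of at least 5 CPM ran from EPHA7, an ephrin receptor gene, at −4.38 (SE 0.21) to OLAH at −2.97 (SE 0.14) on the log2 scale. They included PDGFB, which encodes a platelet-derived growth factor chain and went from 24.4 ± 0.736 to 1.85 ± 0.246 CPM. HEY1, a transcriptional repressor gene induced by Notch, went from 11.1 ± 1.69 to 1.04 ± 0.106 CPM. TNFSF4, the gene of OX40 ligand, fell by 3.40 (SE 0.13), and LIPG, the gene of endothelial lipase, fell by 3.15 (SE 0.10) from 327.4 ± 0.627 to 36.9 ± 2.45 CPM. SLCO2A1, which encodes a prostaglandin transporter, fell by 3.04 (SE 0.14). The others were PPP1R16B (−4.17), TMEM100 (−4.05), IL1RL1 (−4.04), NEBL (−3.17) and NPTX2 (−2.97). The 3′ UTRs of 7 of these 12 genes hold at least 1 leading site that goes with lower values, against 32.97% of all 12053 genes with a 3′ UTR. The sites were picked for their relation to these same fold changes, and UTR length was not matched here. A higher share is therefore no independent evidence.

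The 12 largest rises ran from CPA4, a carboxypeptidase gene, at 3.25 (SE 0.11) to LRRC3 at 2.29 (SE 0.18). CPA4 went from 12.7 ± 1.99 to 121.2 ± 1.23 CPM. They held the collagen genes COL6A6 (2.85) and COL11A1 (2.45), the gene of tumour necrosis factor receptor 2, TNFRSF1B (2.84), and ADAMTSL1 (3.09). DRAM1, a p53-induced regulator of autophagy, went from 10.3 ± 0.987 to 71.8 ± 5.13 CPM. CCNG1, a p53 target that encodes cyclin G1, went from 46.2 ± 0.557 to 254.2 ± 40.9 CPM. SRD5A1, which encodes a steroid 5-alpha-reductase, rose by 2.42 (SE 0.12). The rest were CNIH3 (2.75), PNMA2 (2.69) and TMCO1 (2.67). The 3′ UTRs of 5 of the 12 hold at least 1 of AGCCTTA and CACATCA, the leading sites that go with higher values, against 20.97% of all genes with a 3′ UTR. The same number, 5, of the 12 largest falls hold at least 1 of these, and 2 of the 12 largest rises hold a site that goes with lower values. All these sites were picked from the same fold changes, so the shares are no independent evidence.

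**Figure D2:**
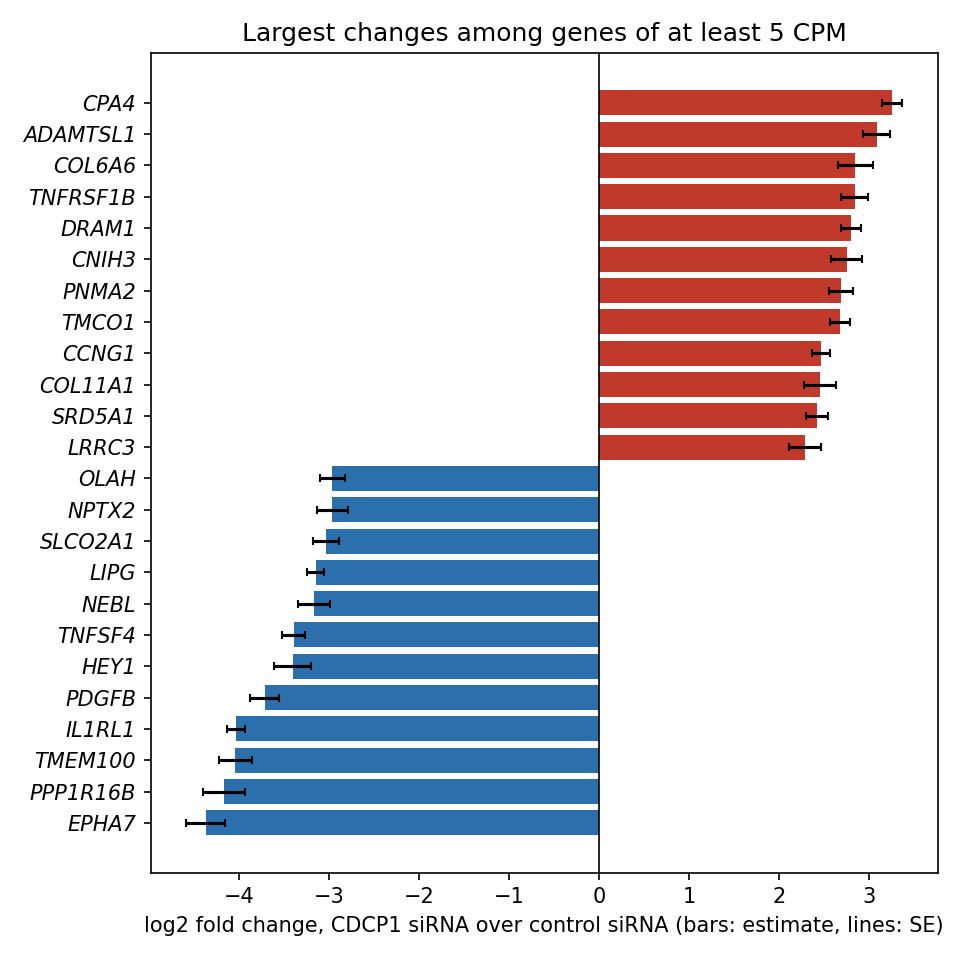
Log2 fold change of the 12 protein-coding genes with the largest rise and the 12 with the largest fall; bars are the estimates and lines their SE from 2 libraries per group. Rises reach 3.25 for CPA4 and falls reach −4.38 for EPHA7.

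Mitotic genes were lower as a group. Of 32 tested members, 31 fell, 0 rose and 1 was not called, with a median of −1.22. Adjusted over the list alone, 31 fell and 0 rose. MKI67, the proliferation marker, went from 106.7 ± 4.95 to 35.5 ± 7.60 CPM (−1.59, SE 0.11). CDC20, KIF20A and CCNB1, genes of the anaphase activator, a mitotic kinesin and cyclin B1, fell by 1.62 (SE 0.11), 1.62 (SE 0.11) and 1.44 (SE 0.11). The member not called was the mitotic transcription factor gene FOXM1, named after its value was seen, at −0.22 (SE 0.12). Against all other genes camera gave an adjusted p of 9.48e-15, and an adjusted p = 0.441 with an estimated correlation. MKI67, CDC20, KIF20A and CCNB1 hold no leading site that goes with lower values, and among the 26 members without one the median was −1.25.

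The DNA replication genes moved the same way, with 24 of 30 members lower, 0 higher and 6 not called; the counts adjusted over the list alone were 24 and 0. The median was −0.92. CDC45 fell by 1.67 (SE 0.15), and the replicative helicase genes MCM6 and MCM7 by 1.27 (SE 0.11) and 1.08 (SE 0.11). MCM6 holds TCTATAA, a leading site that goes with lower values. PCNA, the sliding clamp gene, named after its value was seen, had 59.7 ± 4.39 CPM in the controls and 59.4 ± 0.214 CPM after CDCP1 siRNA. Camera gave an adjusted p of 2.65e-08, and an adjusted p = 0.441 with an estimated correlation. Among p53 targets and cell cycle inhibitors 13 of 25 rose, 5 fell and 7 were not called (14 and 5 adjusted over the list alone), with a median of 0.40. TNFRSF10B, a death receptor gene, rose by 1.36 (SE 0.09), RRM2B by 1.38 (SE 0.10) and BTG2 by 1.24 (SE 0.09), while ZMAT3 fell by 1.19 (SE 0.10). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 and was chosen after its value was seen, rose from 507.2 ± 18.0 to 941.0 ± 16.2 CPM. As a list these were not called (adjusted p = 0.0539), though they were without control siRNA replicate 2 (adjusted p = 0.0261); without each of the other libraries the adjusted p ran from 0.0551 to 0.145.

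Interferon-response genes fell in 24 of 32 members, with 0 rises and 8 not called, both over all genes and adjusted over the list alone, and with a median of −0.87. IFIT1 went from 100.7 ± 6.08 to 30.8 ± 2.97 CPM, and ISG15, a ubiquitin-like modifier gene, from 101.5 ± 24.3 to 32.9 ± 3.47 CPM. IFI6 fell by 1.34 (SE 0.09) and the oligoadenylate synthetase gene OAS3 by 1.28 (SE 0.09). Camera gave an adjusted p of 1.56e-08, and an adjusted p = 0.441 with an estimated correlation. OAS3 holds leading sites of both directions; among the 25 members without a site that goes with lower values the median was −0.85.

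The genes of IL-1 and IL-33 ligands and receptors were lower in 7 of 10 members, with 0 higher and 3 not called, over all genes and adjusted over the list alone alike. Beside IL1RL1, IL18R1 went from 15.8 ± 1.09 to 2.09 ± 0.0201 CPM, a log2 change of −2.91 (SE 0.17). IL1B fell by 1.29 (SE 0.09) and IL1A by 1.36 (SE 0.10). IL33, the ligand of ST2, chosen after its value was seen, went from 40.9 ± 1.90 to 17.4 ± 2.16 CPM. The list had a median of −0.89 and an adjusted p of 0.0121, with an adjusted p = 0.566 with an estimated correlation. Of 30 inflammatory cytokines and NF-kB targets, 13 fell, 9 rose and 8 were not called (14 and 9 adjusted over the list alone), and the list was not called (median −0.20, adjusted p = 0.282). PTGS2, the inducible cyclooxygenase gene, fell by 2.57 (SE 0.10) from 246.2 ± 8.18 to 41.4 ± 7.53 CPM. IL6, of whose exonic length 20.69% overlaps the antisense gene IL6-AS1, fell by 1.84 (SE 0.12). CSF1, the macrophage growth factor gene, chosen after its value was seen, rose by 1.40 (SE 0.10). PTGS2 holds ATCTATA and GAGAAAG, leading sites that go with lower values. The endothelial markers KDR, CDH5 and PECAM1 fell in the same libraries, by 1.24 (SE 0.09), 1.12 (SE 0.11) and 0.88 (SE 0.09). TIE1 and FLT1, the latter chosen after its value was seen, rose by 1.19 (SE 0.13) and 0.81 (SE 0.15). Camera did not call the endothelial list (adjusted p = 0.0859).

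Genes that modify and crosslink collagen were higher, 11 of 18 over all genes with 0 lower and 7 not called, and 12 with 0 lower adjusted over the list alone. PLOD2, a lysyl hydroxylase gene, went from 350.7 ± 13.0 to 994.5 ± 93.5 CPM. The lysyl oxidase genes LOX and LOXL1 rose by 1.07 (SE 0.09) and 1.44 (SE 0.12), and CRTAP, of the prolyl 3-hydroxylase complex, by 0.82 (SE 0.09). The median was 0.55, and camera gave an adjusted p of 7.86e-05, with an adjusted p = 0.441 with an estimated correlation. PLOD2 holds AGCCTTA, a leading site that goes with higher values, whereas LOX holds all 3 that go with lower values.

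Collagens and other matrix proteins went both ways, 15 higher, 9 lower and 8 not called of 32 (16 and 9 adjusted over the list alone), and the list was not called (median 0.18, adjusted p = 0.246). LAMC1, a laminin chain gene, rose from 575.4 ± 21.1 to 2104 ± 80.5 CPM, FBLN2 rose by 1.08 (SE 0.09), and COL11A1 was among the 12 largest rises. THBS1, the thrombospondin gene, fell from 4451 ± 70.5 to 2004 ± 79.0 CPM. The members COL1A1, COL3A1 and POSTN were chosen after their values were seen. COL1A1 rose by 0.45 (SE 0.09), COL3A1 fell by 0.36 (SE 0.08), and POSTN was 3613 ± 169.9 and 3932 ± 167.2 CPM, not called. FN1, chosen likewise, was 65090 ± 3665 and 48950 ± 4394 CPM, a log2 change of −0.41 (SE 0.08, adjusted p = 1.00e-04) that was not called without CDCP1 siRNA replicate 1 (adjusted p = 0.132). Matrix proteases and their inhibitors held 11 rises, 6 falls and 2 members not called of 19, as they did adjusted over the list alone (median 0.31, adjusted p of the list = 0.171). ADAMTS1 rose by 1.57 (SE 0.09) and PLAT, the tissue plasminogen activator gene, by 1.41 (SE 0.09), while ADAMTS4 fell by 1.72 (SE 0.12). PLAU, urokinase, rose by 1.64 (SE 0.17), with 31.05% of its exonic length overlapping C10orf55.

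Contractile and myofibroblast genes were lower in 10 of 18 members, with 1 higher and 7 not called (11 and 1 adjusted over the list alone), and with a median of −0.34. Tropomyosin TPM1 went from 969.4 ± 8.17 to 513.6 ± 13.6 CPM, with 21.44% of its exonic length overlapping TPM1-AS. PALLD, CNN2 and the myosin light chain gene MYL9 fell by 0.94 (SE 0.09), 0.90 (SE 0.09) and 0.79 (SE 0.09). ACTA2, smooth muscle actin, chosen after its value was seen, went from 49.9 ± 0.264 to 32.0 ± 4.51 CPM, with 30.11% of its exonic length overlapping ACTA2-AS1. Camera gave an adjusted p of 8.20e-03, and an adjusted p = 0.441 with an estimated correlation. In a test added after the data were seen, on the 9 members with a 3′ UTR and none of the leading sites, the list was not called (adjusted p = 0.0744), with a median of −0.29 and 9 fewer members.

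The TGF-beta list was divided, with 6 rises, 9 falls and 7 members not called of 22 (8 and 9 adjusted over the list alone), and was not called (median −0.05, adjusted p = 0.412). INHBA, the inhibin beta A gene, and SMAD7, an inhibitor of the pathway, fell by 1.83 (SE 0.12) and 0.98 (SE 0.11), while the receptor gene TGFBR1 rose by 1.06 (SE 0.12). INHBA, SMAD7 and TGFBR1 hold GAGAAAG, and TGFBR1 also holds TCTATAA and CACATCA, the latter a site that goes with higher values. CCN2, chosen after its value was seen, fell by 0.29 (SE 0.08). The BMP list was lower in 8 of 14 members with 2 higher and 4 not called (9 and 2 adjusted over the list alone), with a median of −0.33. BMP6 went from 69.6 ± 2.85 to 17.6 ± 1.28 CPM, BMP2 fell by 1.43 (SE 0.11), the target gene ID3 by 0.92 (SE 0.10), and GREM1, a BMP antagonist gene, by 1.20 (SE 0.14). Camera gave the BMP list an adjusted p of 0.0116, and an adjusted p = 0.441 with an estimated correlation; among the 5 members with a 3′ UTR and none of the leading sites the adjusted p was 0.0841 and the median −0.33. YAP/TAZ targets were higher in 5, lower in 9 and not called in 9 of 23, the same adjusted over the list alone (median −0.09, adjusted p of the list = 0.389). ANKRD1, NT5E and the tissue factor gene F3 fell by 1.24 (SE 0.09), 0.89 (SE 0.09) and 1.13 (SE 0.12), and AXL rose by 0.70 (SE 0.09).

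Adhesion genes rose in 17 of 25 members, fell in 4 and were not called in 4 (17 and 5 adjusted over the list alone), with a median of 0.60. The integrin beta 1 gene ITGB1 went from 2302 ± 90.4 to 4533 ± 138.9 CPM. CDH11, cadherin 11, rose by 1.43 (SE 0.09) and MCAM by 1.32 (SE 0.10), while ITGB8 fell by 1.75 (SE 0.11). Camera gave an adjusted p of 1.89e-03, and an adjusted p = 0.441 with an estimated correlation. Signalling partners of CDCP1 were higher in 9 of 20 members, lower in 2 and not called in 9, as they were adjusted over the list alone. CTNNB1, beta-catenin, went from 234.2 ± 9.22 to 496.6 ± 8.37 CPM, and YES1, a kinase gene of the SRC family, from 94.6 ± 0.906 to 190.6 ± 23.9 CPM. The partner list had a median of 0.20 and an adjusted p of 0.0258, with an adjusted p = 0.441 with an estimated correlation. Among its 9 members with a 3′ UTR and none of the leading sites the adjusted p was 0.228 and the median 0.15, with fewer members tested.

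Growth factor genes and their receptors were not called as a list (adjusted p = 0.92), with 8 higher, 8 lower and 10 not called of 26 (9 and 8 adjusted over the list alone). Their median was 0.09 and their mean −0.17, and the test pointed down like the mean. Beside PDGFB, IGFBP5 fell from 156.3 ± 3.37 to 23.2 ± 0.391 CPM, the EGF receptor ligand gene AREG from 707.9 ± 36.7 to 192.7 ± 2.02 CPM, and KITLG by 1.88 (SE 0.16). Immediate early genes and ERK feedback genes held 6 rises, 10 falls and 9 members not called of 25 (7 and 10 adjusted over the list alone), with a median of −0.10 (adjusted p of the list = 0.389). SPRY1 and EGR1 fell by 1.48 (SE 0.12) and 1.38 (SE 0.13), and FOSL1 rose by 1.03 (SE 0.10). The phosphatase gene DUSP6, with 40.48% of its exonic length overlapping another gene, fell by 0.70 (SE 0.10). FOXO targets held 5 rises, 11 falls and 6 not called of 22, the same adjusted over the list alone, and the list was not called (median −0.26, adjusted p = 0.234). PIK3IP1 fell by 1.89 (SE 0.13), the ubiquitin ligase gene FBXO32 by 1.26 (SE 0.11) and IRS2 by 1.12 (SE 0.10), whereas TXNIP rose by 0.75 (SE 0.09).

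Genes of cholesterol synthesis were lower in 13 of 23 members, with 1 higher and 9 not called (14 and 1 adjusted over the list alone), with a median of −0.33. SC5D, FDFT1 and FDPS fell by 1.04 (SE 0.10), 0.66 (SE 0.09) and 0.62 (SE 0.09). Camera gave an adjusted p of 8.36e-03, and an adjusted p = 0.441 with an estimated correlation. Among the 14 members with a 3′ UTR and none of the leading sites the adjusted p was 0.0698 and the median −0.26. Fatty acid synthesis held 3 rises, 6 falls and 6 members not called of 15, over all genes and adjusted over the list alone (median −0.09, adjusted p of the list = 0.332). ME1, malic enzyme, fell by 1.37 (SE 0.11), ACSL3 by 0.74 (SE 0.09) and the ATP citrate lyase gene ACLY by 0.56 (SE 0.09), and ELOVL6 rose by 0.87 (SE 0.10). Glycolysis and hypoxia genes were higher in 12 of 25 members, lower in 3 and not called in 10 (13 and 3 adjusted over the list alone), with a median of 0.22. CA12, a carbonic anhydrase gene, and ENO2 rose by 1.33 (SE 0.09) and 1.32 (SE 0.10), hexokinase HK2 by 0.87 (SE 0.09), and VEGFA fell by 0.90 (SE 0.09). The glycolysis list had an adjusted p of 0.0256, and an adjusted p = 0.441 with an estimated correlation. It was not called without control siRNA replicate 2 (adjusted p = 0.0674) or without CDCP1 siRNA replicate 2 (adjusted p = 0.0551).

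Oxidative phosphorylation genes were higher in 2, lower in 7 and not called in 21 of 30 (1 and 7 adjusted over the list alone), and the list was not called (median −0.06, adjusted p = 0.412). COX7C, NDUFB10 and COX4I1 were at −0.32 (SE 0.09), −0.33 (SE 0.10) and −0.25 (SE 0.09); without control siRNA replicate 1 none of them was called (adjusted p = 0.159, 0.0705 and 0.182). Without CDCP1 siRNA replicate 1, NDUFB10 and COX4I1 were not called (adjusted p = 0.0699 and 0.302). Stress-response genes of the unfolded protein and integrated stress pathways held 9 rises, 10 falls and 9 members not called of 28, over all genes and adjusted over the list alone (median −0.16, adjusted p of the list = 0.389). SLC7A11, the cystine transporter gene, fell from 140.4 ± 0.228 to 46.4 ± 5.21 CPM, while VLDLR rose by 1.01 (SE 0.10). HERPUD1, of endoplasmic reticulum protein degradation, and PSAT1, of serine synthesis, went from 105.4 ± 8.92 to 56.6 ± 1.28 CPM and from 40.0 ± 1.21 to 19.4 ± 1.09 CPM.

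Autophagy and lysosome genes were higher in 10, lower in 4 and not called in 10 of 24 (10 and 5 adjusted over the list alone), with a median of 0.07 (adjusted p of the list = 0.178). The lysosomal membrane genes LAMP1 and LAMP2 rose from 193.5 ± 11.5 to 518.9 ± 14.6 CPM and from 98.8 ± 0.265 to 300.9 ± 30.4 CPM. GPNMB rose by 1.19 (SE 0.10), and WIPI1, with 28.07% of its exonic length overlapping ARSG, by 1.21 (SE 0.11). LAMP1 holds AGCCTTA, and LAMP2 holds CACATCA as well as GAGAAAG. Apoptosis regulators held 6 rises, 8 falls and 6 not called of 20, the same adjusted over the list alone, and were not called as a list (adjusted p = 0.64); their median was 0.05, their mean −0.10, and the test pointed down. The inhibitor of apoptosis genes BIRC5 and XIAP fell by 1.18 (SE 0.13) and 0.85 (SE 0.11), and BCL2L1, whose exonic length overlaps ABALON by 42.97%, rose by 0.85 (SE 0.09).

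Among heart failure plasma markers 5 rose, 3 fell and 7 were not called of 15 (7 and 3 adjusted over the list alone), and the list was not called (median 0.20, adjusted p = 0.127). Beside IL1RL1 and TNFRSF1B, IGFBP7 rose by 0.75 (SE 0.08) and adrenomedullin ADM fell by 0.88 (SE 0.12). Cardiac fibroblast identity genes held 5 rises, 7 falls and 7 members not called of 19 (5 and 8 adjusted over the list alone), with a median of −0.05 (adjusted p of the list = 0.449). PDGFRA, the fibroblast receptor gene, went from 218.8 ± 10.7 to 110.5 ± 0.968 CPM. FAP and DPP4, both serine protease genes, rose by 0.92 (SE 0.10) and 0.82 (SE 0.09). VIM, vimentin, chosen after its value was seen, had 1894 ± 76.6 and 2050 ± 75.1 CPM and was not called, with 24.43% of its exonic length overlapping VIM-AS1.

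Some markers of other cell types passed the low-count filter, and these moved in both directions. Tested were 12 of 13 listed endothelial, 5 of 11 pericyte and smooth muscle, and 9 of 13 epicardial and mesothelial markers. Of the cardiomyocyte and leukocyte markers, 1 of 16 and 3 of 15 were tested. Of 12 endothelial markers 6 fell, 2 rose and 4 were not called, over all genes and adjusted over the list alone. Camera did not call the list (adjusted p = 0.0859, median −0.72), though it did with limma voom and with the replicate block (adjusted p = 0.0214 and 0.0404). KDR, a VEGF receptor gene, went from 428.6 ± 16.5 to 181.9 ± 4.52 CPM, PECAM1 from 117.0 ± 3.54 to 63.8 ± 1.85 CPM, and CDH5 from 41.6 ± 0.0844 to 19.1 ± 1.62 CPM, while TIE1 rose from 9.99 ± 0.552 to 22.8 ± 1.55 CPM. VWF, chosen after its value was seen, had 0.359 ± 0.107 and 0.222 ± 0.0454 CPM. Of 5 pericyte and smooth muscle markers 4 rose, 1 fell and 0 were not called, the same adjusted over the list alone, with a median of 1.93 (adjusted p = 0.027, and adjusted p = 0.517 with an estimated correlation). CSPG4 had 2.30 ± 0.112 and 8.84 ± 0.0579 CPM, KCNJ8 0.664 ± 0.209 and 4.30 ± 0.122 CPM, and NOTCH3 rose by 0.81 (SE 0.10). ABCC9 was at 1.93 (SE 0.55), and RGS5, chosen after its value was seen, at −1.27 (SE 0.38); without control siRNA replicate 2 neither was called (adjusted p = 0.106 and 0.405), nor by DESeq2 (adjusted p = 0.0642 and 0.0753). The pericyte list was not called without CDCP1 siRNA replicate 2 (adjusted p = 0.0551) or without a filter on low counts (adjusted p = 0.368).

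Of 9 epicardial and mesothelial markers 3 rose, 4 fell and 2 were not called, also adjusted over the list alone (adjusted p of the list = 0.45, median 0.08, mean −0.15), and the test pointed down like the mean. Keratin KRT7 fell from 820.2 ± 51.2 to 378.3 ± 29.4 CPM and KRT18 by 1.24 (SE 0.10), with KRT8 at −0.94 (SE 0.13) and ALDH1A2, a retinaldehyde dehydrogenase gene, at −1.16 (SE 0.14). The only cardiomyocyte marker past the filter was TTN, at 13.7 ± 0.226 and 15.2 ± 0.478 CPM and not called, with 0 rises and 0 falls over all genes or adjusted over the list alone. Of 3 leukocyte markers past the filter 0 rose and 2 fell, CD14 and CSF1R, over all genes and adjusted over the list alone. Both were low, CD14 at 2.68 ± 0.645 and 1.24 ± 0.0425 CPM and CSF1R at 0.785 ± 0.167 and 0.312 ± 0.240 CPM. CD68, with 85.79% of its exonic length overlapping another gene, was at −0.18 (SE 0.12) and not called. CD14 was not called without control siRNA replicate 2 (adjusted p = 0.0628), and CSF1R was not called without control siRNA replicate 1, control siRNA replicate 2 or CDCP1 siRNA replicate 1 (adjusted p = 0.354, 0.0921 and 0.355), nor by DESeq2 (adjusted p = 0.225), with library totals alone (0.0503) or with the replicate block (0.0592). Both lists were too short to test.

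**Figure D3:**
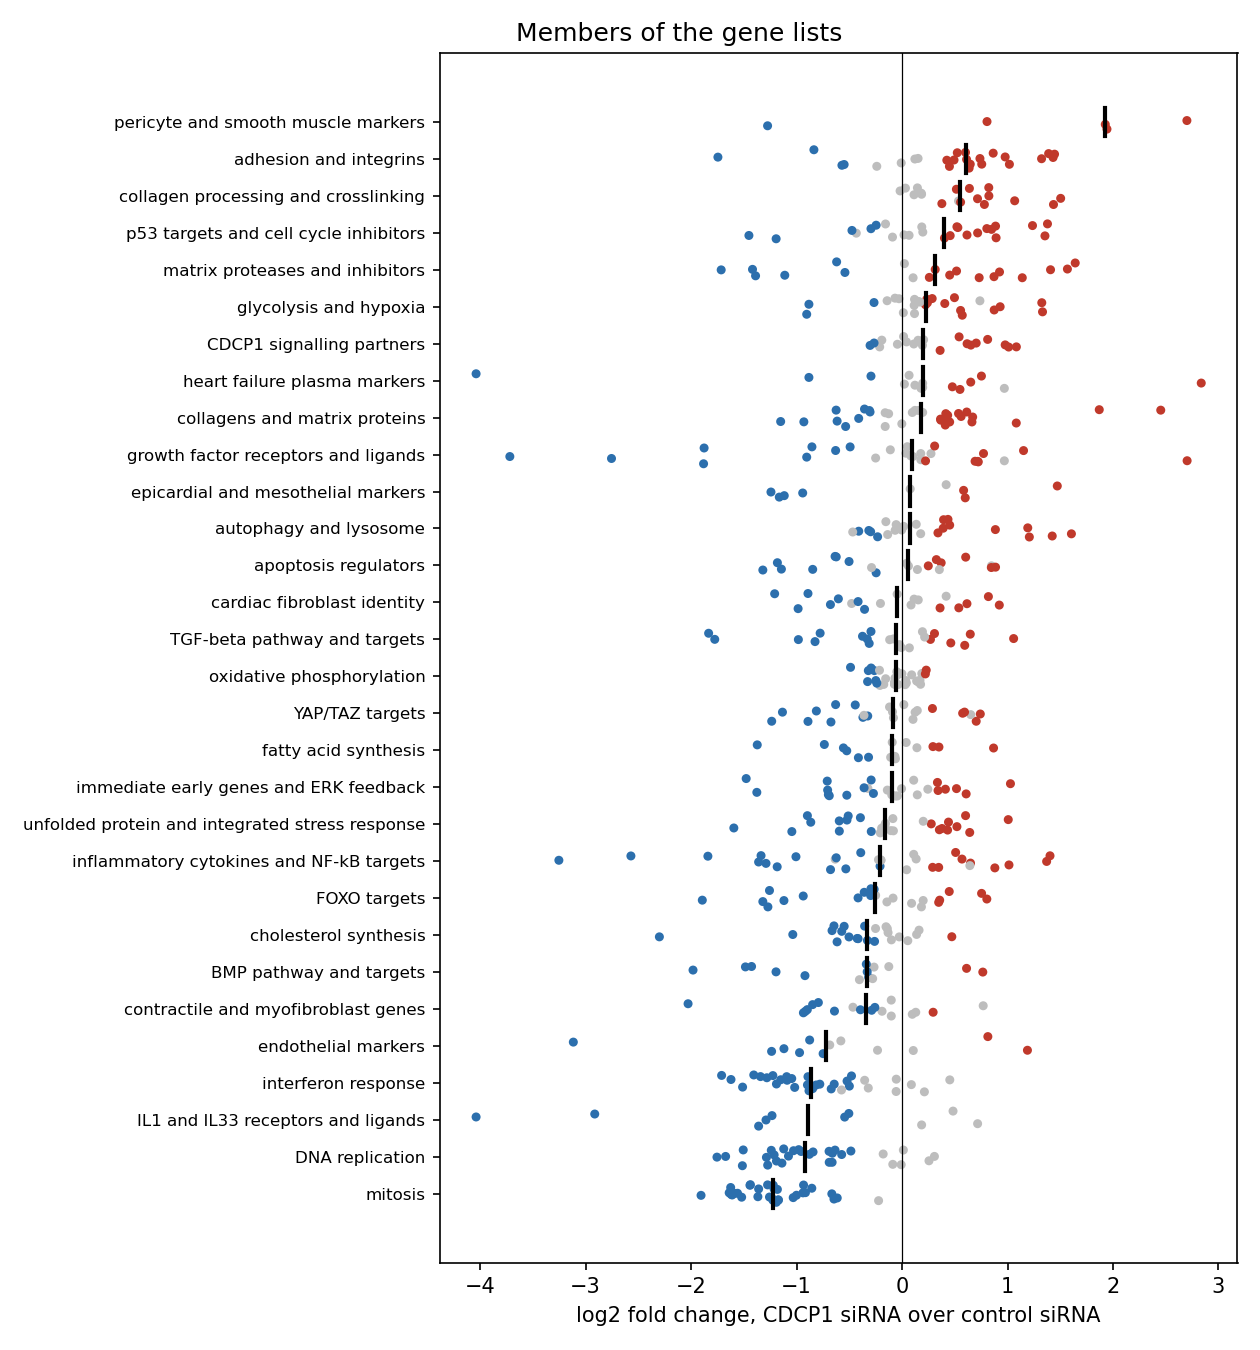
Log2 fold change of each tested member of the 30 gene lists tested, ordered by median; red points rose, blue points fell and grey points were not called at an adjusted p under 0.05 (edgeR, 2 libraries per group), and black lines are list medians. Mitosis lies lowest, with a median of −1.22 and 31 of 32 members lower.

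With the correlation between genes estimated from the 4 libraries, which leaves few degrees of freedom, 0 of the 12 list calls passed. The interferon list had an estimated correlation of −0.0226, below the preset 0.01, yet its unadjusted camera p went from 1.04e-09 to 0.0199. Where lists share an adjusted p of 0.441, the adjustment over lists made them equal. Their unadjusted camera p with an estimated correlation ran from 0.0199 for interferon to 0.147 for adhesion. Fry, which does not compare a list with other genes, called 26 lists. The libraries of a group differed by more than counting error, with a chi-square per degree of freedom of 8.61 in the control pair and 14.3 in the CDCP1 siRNA pair.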

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

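The alternative with genes that hold no leading 3′ UTR site was chosen after the data were seen; the others were set before. Between 2723 and 4084 genes were higher and between 2714 and 3948 lower over all settings, each within 1.5 times the count reported. The lowest counts came without control siRNA replicate 2 (2723 higher) and at an adjusted p under 0.01 (2714 lower). Without each library in turn, 2723 to 4051 genes were higher and 2758 to 3825 lower. DESeq2 called 3167 higher and 2787 lower, of which 3154 and 2751 were among those reported. The log2 fold change of CDCP1 ran from −3.09 to −2.86. With the replicate number as a block, 3995 genes were higher, 3689 lower, and 13 lists were called. Of 12 lists called, camera called 0 with an estimated correlation, when fry called 26; among genes without a leading site it called 7, with fewer members in each list, and the pericyte list had too few members left for a value. The remaining settings called 10 to 16 lists. The p53 list was called with RLE factors (adjusted p = 0.0493), without a filter (0.0201), with the stricter filter (0.0402) and by voom (0.00813). The endothelial list was called with the block (adjusted p = 0.0404) and by voom (0.0214), and voom also called matrix proteases (0.0256) and autophagy (0.0157); the cause was not tested. Robust estimation does not enter camera, so it gave no list value. No named gene or list changed direction where either the reported test or the alternative called it. Uncalled lists could still turn. The TGF-beta, YAP/TAZ, fibroblast identity, growth factor, FOXO and apoptosis lists pointed down over all genes and up among genes without a leading site. Of the 168 genes taken by the rules or chosen later, those past the threshold stayed past it in each setting that tested them except ABCC9, CD14, COX4I1, COX7C, CSF1R, FN1, MT2A, NDUFB10 and RGS5, each lost in at least 1 setting; the stricter filter removed ABCC9, CSF1R, EMCN and VWF, and DESeq2 gave no adjusted p for VWF. Without a filter on low counts the median log2 fold change of the genes tested moved to −0.08. With 2 libraries per group and 34078629 to 42156048 counts, the simulation recovered 63.64% of changes of 1.5-fold, so some small changes may be missed. It changed 200 of 19298 genes, whereas 40.6% of the genes were called in the data, so that rate may not hold for them.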

Other observations

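The gene families in these 2 paragraphs, and the genes named here for the first time, were chosen after the values were seen. Families were formed by gene symbol alone, so their members may differ in function. Of 15 tested Notch receptors, ligands and HES or HEY targets, 7 fell, 3 rose and 5 were not called, with a median of −0.93. The Notch-induced repressor genes HEYL, HEY1 and HES1 fell by 5.58 (SE 0.50), 3.41 (SE 0.21) and 2.10 (SE 0.18), the ligand gene JAG1 went from 243.2 ± 0.0672 to 117.6 ± 0.660 CPM, and the receptor gene NOTCH4 fell by 1.69 (SE 0.18). NOTCH2 and NOTCH3 rose by 0.84 (SE 0.09) and 0.81 (SE 0.10). In the same libraries the endothelial markers KDR, CDH5, PECAM1 and EMCN fell by 1.24 (SE 0.09), 1.12 (SE 0.11), 0.88 (SE 0.09) and 3.12 (SE 0.58), EMCN from 1.10 ± 0.419 CPM. TIE1 and FLT1 rose by 1.19 (SE 0.13) and 0.81 (SE 0.15), and TEK was not called. Camera did not call the endothelial list (adjusted p = 0.0859). The pericyte list, to which NOTCH3 belongs, had a median of 1.93 over 5 members, of which 4 rose and 1 fell. That median is the value of ABCC9, which had 0.202 CPM in the controls and 0.784 CPM after CDCP1 siRNA. HEYL holds GAGAAAG, and HEY1 and HES1 hold none of the leading 7-base sites. Over the 20 families tested, camera gave the Notch family an adjusted p of 0.0386, and an adjusted p = 0.571 with an estimated correlation. Among 18 genes of a prostaglandin family formed by symbol, 9 fell and 0 rose (camera adjusted p = 0.0403, and adjusted p = 0.571 with an estimated correlation). The falls counted include PTGFRN, PTGES3, PTGR1 and PTGR3, whose part in prostaglandin synthesis, transport or reception was not checked. PTGS1, the constitutive cyclooxygenase gene, went from 418.0 ± 8.78 to 106.0 ± 7.13 CPM, beside the falls of PTGS2 and SLCO2A1.

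Kinesins fell in 16 of 29 members and rose in 4 (adjusted p = 0.00875, and adjusted p = 0.571 with an estimated correlation), led by KIF2C at −1.91 (SE 0.14). KIF2C, KIF20A, KIF11 and KIF23 also belong to the mitosis list. Tubulins fell in 9 of 15 with 0 rises (adjusted p = 0.0316, and adjusted p = 0.628 with an estimated correlation), the largest fall being that of TUBA4A at −1.15 (SE 0.10). Metallothioneins rose in 6 of 8 and fell in 1, without passing as a family (adjusted p = 0.0863). MT1E went from 49.2 ± 2.39 to 172.1 ± 4.02 CPM, and MT2A, the one that fell, from 594.7 ± 70.5 to 490.9 ± 21.9 CPM, a fall not called without control siRNA replicate 2 (adjusted p = 0.28). Among 3250 long non-coding genes 433 rose and 369 fell. MEG3 went from 100.2 ± 2.88 to 345.0 ± 1.87 CPM and LINC01614 from 9.67 ± 0.305 to 0.601 ± 0.0117 CPM.

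Of the tests below, that of endothelial cells was chosen only after the result was seen; the others were set before their values were computed, though the follow-up of the 5 leading sites came after the search that found them.

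Genes that fell more often held certain 7-base sites in the 3′ UTR, led by ATCTATA with a statistic of −10.51 (shuffles reached −5.35), and so did genes that rose, led by AGCCTTA with 9.67 (shuffles reached 5.60), as off-target repression through the seeds of the CDCP1 siRNA and of the control siRNA, or release from a microRNA, would give. Between libraries of 1 group the 5 leading sites did not stand out, with a largest statistic of 2.05 for the low-side and 1.23 for the high-side sites. These sites were picked for standing out between the groups, and no others were examined within a group. Chance differences between libraries are therefore not excluded. A composition bias of whole transcripts as the whole cause is argued against for the high-side sites, whose largest ratio of coding-sequence to 3′ UTR statistic was 0.44. AGCCTTA, which gave that ratio, still had a coding-sequence statistic of 4.23, with 916 genes holding it there and 1407 in the 3′ UTR. A part of such a bias is thus not excluded for AGCCTTA, and the bias stays open for GAGAAAG, which gave the low-side ratio of 0.75. The sites account for 3.13% of the variance of the regressed fold changes, and 386 of 671 genes lower by at least 1 log2 unit and 304 of 507 higher by as much hold no site of their direction. A low-side site was held by 42.47% of these lower genes and 29.74% of uncalled genes, and a high-side site by 40.04% of the higher genes and 17.42% of uncalled genes. These shares come from the data that picked the sites. The siRNA sequences are not given in the sources used here, and loss of CDCP1 itself could not be tested apart from them, since each group received 1 reagent.

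The mitosis, DNA replication and interferon lists fell, and a candidate explanation is direct repression of their members through the low-side sites. The medians of members without such a site argue against it as the whole cause. They were −1.247 for mitosis (95% bootstrap interval −1.44 to −1.182), −0.844 for DNA replication (−1.029 to −0.661) and −0.848 for the interferon response (−1.15 to −0.479). The intervals resample the members of a list as if independent and do not cover variation between libraries. Only the leading low-side sites were considered. Repression of an upstream regulator, a response to 1 of the siRNAs as foreign RNA, and loss of CDCP1 remain open and were not tested.

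The endothelial markers KDR, PECAM1 and CDH5 fell, which could reflect a lower share of endothelial cells after CDCP1 siRNA. Such a loss as the only change would lower the markers alike. Their log2 fold changes spread with a Cochran's Q of 443.7 against a 95% limit of 19.7, and 2 markers, TIE1 and FLT1, rose with intervals above 0. With 40.6% of all tested genes called, such a spread could also arise beside a loss of these cells, so Q cannot decide on it. TEK, at 46.3 ± 2.37 and 49.9 ± 2.75 CPM, was not called; TEK, FLT1 and EMCN were chosen after their values were seen. A lower share of such cells would not by itself raise TIE1 and FLT1, but as a cause of the falls it stays open. So do a change of expression within the fibroblasts and effects on single genes. PECAM1, CDH5 and EMCN, which fell, hold low-side sites, FLT1, which rose, holds 1 of each side, and KDR, which fell, holds a high-side site alone.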
